A study of Mus musculus with 10 samples.

How the data were processed

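Low-coverage whole genome sequencing was made from 8 ovarian tumors, and single-cell RNA sequencing from the ascites of 1 mouse after red cells were removed. A library of normal fallopian tube and uterus is listed in the labels, and was not analysed here. The submitters' processing notes name BWA, Picard, Cell Ranger and Seurat 2.3.4 and the build GRCm38 (mm10). The tool that turned coverage into copy ratios is not given in the sources used here.

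The authors deposited a log2 copy ratio per bin for each tumor, per the file headers. The authors also deposited the read depth of each bin, a coverage signal, and a bin weight, a score that was identical in the 8 tables and was not used. The tables hold 59640 bins that cover 1028 Mb of genes on chromosomes 1 to 19 and X. What the log2 ratio was taken against is not given in the sources used here. The authors deposited markers of 9 ascites clusters as an average log fold change, read here as a natural log, the scale of the Seurat version in the submitters' processing notes. The lowest listed value was 0.50, so weaker markers are not seen. The authors deposited copy number regions of the ascites cells with a state score. States above 3 were read as gain and states under 3 as loss, which the file headers do not state. Spreadsheet software had turned 6 marker names into dates, and these were not used.

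Bins of depth 0, between 7 and 50 per tumor, hold a placeholder log2 value and were treated as missing, a choice made after the values were seen. Medians of the bins in 1 Mb windows gave 2346 windows with a median of 26 bins, and 371 windows had fewer than 10. A window was altered above 0.2 or below -0.2. Gene positions came from a RefSeq table of the same build, and a gene's value is the median of its bins. Counts of list genes per tumor, and oncogenes against tumor suppressors, used the 1 Mb window that holds the gene.

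Groups were compared by exact two-sided permutation of the difference of means, over 56 splits for Lkb1 and 70 for PAX8. The smallest p is then 0.0357 and 0.0286. The largest 5 Mb window difference was set against its maximum in every split, with mirrored PAX8 splits counted once (35). Sharing between tumors, gene lists and ascites regions were set against 10000 random shifts along the joined genome. Benjamini-Hochberg adjustment was used. The tests, gene lists and main settings were fixed before the data were examined, except where stated. Not fixed in advance were the tests of gained and lost shares, depth, noise and counts of altered chromosomes. The test of changes of state between neighbouring windows was planned for Lkb1 and not for PAX8. Named genes were edit targets (among them Brca1, Trp53 and Stk11, of which the labels name the last, as Lkb1), list genes past 0.2 the same way in at least 4 tumors (at most 20 by mean log2), list genes past 1 or below -1 in any tumor, and the highest and lowest 1 Mb window of each tumor. For ascites they were the 3 leading genes of each cluster and counts of list members with examples. Results for some genes that the rule names were left out of the text.

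The functions were tested on 50 simulated sets of 8 tumors with the real 59640 bins. The planted group difference had p under 0.05 in 50 sets, the altered share erred by at most 4.00 percentage points, and sets without shared changes had a shift p under 0.05 in 2. These figures hold for the simulated changes and noise, whose sizes are not given here. They do not measure the error for real values close to the threshold. Alternatives were other thresholds, recentring, 5 and 10 Mb windows, autosomes only, splits within the other label, each tumor left out, and limma 3.58.1 in R 4.3.3 for chromosome means. Keeping bins of depth 0, requiring at least 10 bins per window and splitting within endings of the tumor numbers were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.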

Results

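Ovarian tumors were raised in C57BL/6 mice by electroporating plasmids for Cas9, guide RNA and Cre into the fallopian tube epithelium. DNA from 8 fixed, embedded tumors was sequenced at low coverage, and each tumor carries 2 labels. Lkb1, the kinase encoded by Stk11, was deleted in 5 tumors and intact in 3. By their labels 4 tumors were positive and 4 negative for PAX8, a transcription factor used as a marker of the fallopian tube epithelium. The labels cross: 2 Lkb1-deleted and 2 Lkb1-intact tumors were PAX8-positive, and 3 Lkb1-deleted and 1 Lkb1-intact tumors were PAX8-negative. Ascites cells from 1 mouse, whose label carries the number of Lkb1-deleted tumor 1, were profiled by single-cell RNA sequencing. Mean depth over the bins ran from 1.27 in Lkb1-deleted tumor 1 to 2.26 in Lkb1-deleted tumor 5. The spread between neighbouring bins ran from an SD of 0.16 to 0.26 on the log2 scale, so single bins carry an error close to the 0.2 threshold used here. Medians of 1 Mb windows had a spread of 0.05 to 0.10. Each tumor has its own number in the labels, and p-values of group comparisons measure the spread between these tumors. P-values from random shifts along the genome hold the tumors fixed and do not measure that spread.

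PAX8-positive tumors carried many more copy number changes than PAX8-negative tumors. In PAX8-positive tumors 44.1% ± 6.25 (SD, n = 4) of 1 Mb windows lay past 0.2 or below -0.2 on the log2 scale, against 9.68% ± 4.24 (SD, n = 4) in PAX8-negative tumors, and the exact two-sided permutation p was 0.0286. The groups did not overlap, since the lowest positive tumor stood at 34.9% and the highest negative tumor at 13.2%. Gains covered 18.0% of windows (15.6% to 22.0%, n = 4) against 3.54% (2.22% to 5.12%, n = 4), with an exact permutation p of 0.0286. Losses covered 26.1% (16.2% to 32.0%, n = 4) against 6.14% (1.49% to 9.93%, n = 4), with the same exact permutation p of 0.0286. Changes of state between neighbouring windows numbered 500 ± 91.9 against 248 ± 106 (SD, n = 4 each, exact permutation p = 0.0286). Isolated windows add to this count: Lkb1-intact tumor 1 had 365 changes of state with 227 altered windows and 0 chromosomes altered over most of their windows. PAX8-positive tumors had 6.25 ± 1.5 chromosomes gained or lost over most of their windows and PAX8-negative tumors 0.5 ± 0.58 (SD, n = 4 each, exact permutation p = 0.0286). This p is the smallest that 4 against 4 tumors can give, and over the 8 comparisons of shares and breakpoints the Benjamini-Hochberg adjusted value was 0.0571. Of the PAX8 measures tested here, only the altered share was planned. Mean depth was 1.44 ± 0.13 in positive and 1.84 ± 0.41 in negative tumors (SD, n = 4 each, exact permutation p = 0.171). Window noise was 0.084 ± 0.008 in positive and 0.065 ± 0.021 in negative tumors (SD, n = 4 each, exact permutation p = 0.2). Splitting only within Lkb1-deleted and Lkb1-intact tumors left the difference at 34.5 percentage points with an exact p of 0.0667, the smallest that those splits allow. The numbers of the tumors share 4-digit endings, whose meaning the labels do not give. Among tumors with the same ending the difference was 36.7 points in 1 set (2 positive, 1 negative) and 35.9 in another (1 and 1), and the other endings hold 1 PAX8 group each.

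**Figure D1:**
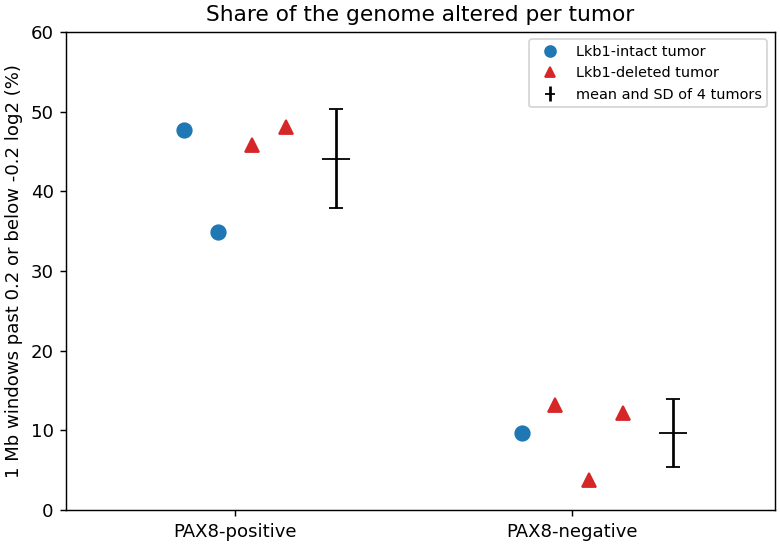
Percent of 1 Mb windows with a log2 copy ratio above 0.2 or below -0.2 in each tumor (points, circles Lkb1-intact and triangles Lkb1-deleted), with the mean and SD of 4 tumors per PAX8 group beside them. The 4 PAX8-positive tumors sit between 34.9% and 48.1%, and the 4 PAX8-negative tumors between 3.71% and 13.2%.

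Changes over most of a chromosome were frequent in PAX8-positive tumors. Lkb1-deleted tumor 1 had losses of chromosomes 12 (mean log2 -0.73), 13 (-0.60) and 18 (-0.57), with gains of 15 (0.39) and 17 (0.27). Lkb1-deleted tumor 4 had losses of 13 (-0.48), 7 (-0.47) and 10 (-0.41) and gains of 17 (0.36) and 3 (0.30). Lkb1-intact tumor 2 had losses of X (-0.64) and 13 (-0.56), and Lkb1-intact tumor 3 a loss of 14 (-0.28) and a gain of 11 (0.24). Among PAX8-negative tumors, Lkb1-deleted tumors 2 and 5 each had 1 such change, a loss of chromosome 16 (-0.28 and -0.22), and the other 2 had 0. Lkb1-deleted tumor 2 had a run of 33 lost windows on chromosome 2 from 59000001 to 93000000 (mean log2 -0.62). Lkb1-deleted tumor 5 had a run of 59 gained windows on chromosome 1 from 63000001 to 131000000 (mean log2 0.38). The longest loss in Lkb1-deleted tumor 3 spanned 5 windows on chromosome 7 from 128000001 to 133000000 (mean log2 -0.71). These runs were chosen after their values were seen, and positions are in the mouse build GRCm38.

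**Figure D2:**
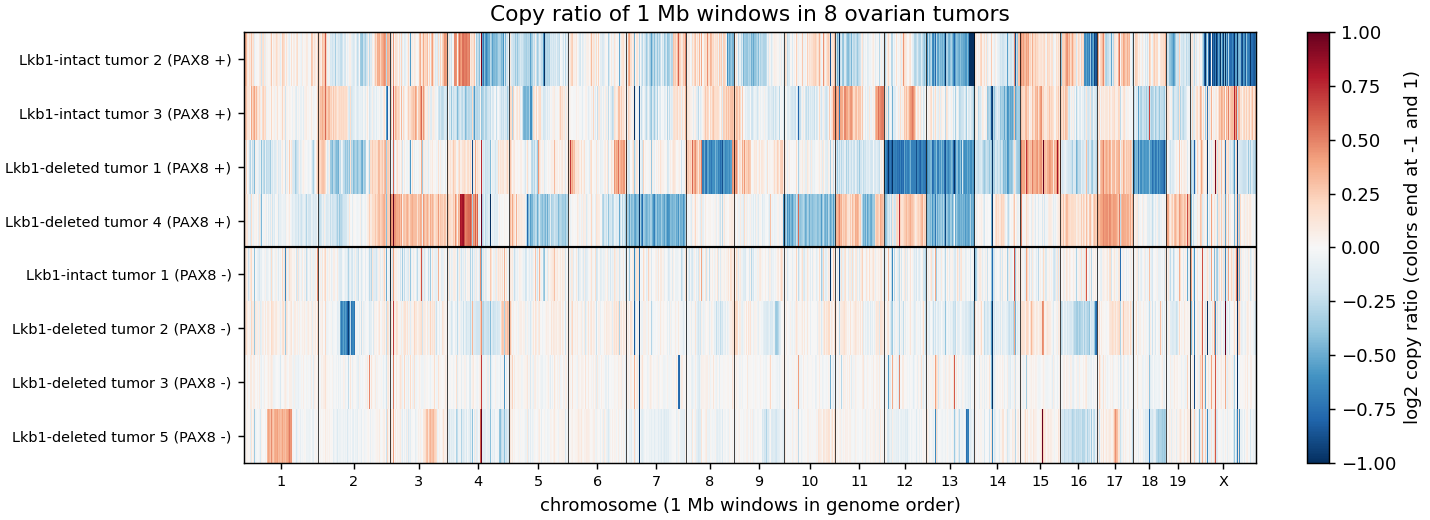
Log2 copy ratio (color) of 1 Mb windows (x axis, in genome order) in the 8 tumors (rows), with PAX8-positive tumors above the line and PAX8-negative tumors under it. Broad gains and losses run through the upper 4 tumors, while Lkb1-intact tumor 1 and Lkb1-deleted tumor 3 have 9.68% and 3.71% of windows altered.

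Lkb1 status did not separate the tumors by the share of windows altered. Lkb1-deleted tumors had 24.6% ± 20.8 (SD, n = 5) of windows altered and Lkb1-intact tumors 30.7% ± 19.3 (SD, n = 3), with an exact two-sided permutation p of 0.857. The sign of this difference turned within PAX8 groups, where Lkb1-deleted tumors were higher by 2.85 percentage points (exact p = 0.417), and without Lkb1-intact tumor 2 (2.32 percentage points). Changes of state between neighbouring windows numbered 296 ± 136 (SD, n = 5) in Lkb1-deleted and 504 ± 125 (SD, n = 3) in Lkb1-intact tumors, with an exact permutation p of 0.107. Within PAX8 groups the difference was -152 (exact p = 0.0833, the smallest those splits allow), and each Lkb1-intact tumor stood above each Lkb1-deleted one, at 541 and 607 against 451 and 401 in positive and 365 against 309, 142 and 175 in negative tumors. Window noise was ordered the same way in both PAX8 groups, at an SD of 0.064 in Lkb1-deleted and 0.091 in Lkb1-intact tumors (exact permutation p = 0.0357). Over all tumors the difference in changes of state was -209 in the main setting. It shrank to -89.6 at a threshold of 0.3 (exact permutation p = 0.25) and to -27.7 in 5 Mb windows (exact permutation p = 0.214).

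No chromosome differed between groups after adjustment, and with a smallest exact p of 0.0357 or 0.0286 at least 15 chromosomes by Lkb1 or 12 by PAX8 would need that p to pass. Chromosome 13 had the largest mean difference by PAX8, at -0.43 ± 0.23 in positive against -0.06 ± 0.07 in negative tumors (SD, n = 4 each, exact permutation p = 0.0571, Benjamini-Hochberg adjusted 0.429 over 20 chromosomes). Its limma p was 0.00286, adjusted 0.0572 by the Benjamini-Hochberg method. Chromosome 5 was at -0.13 ± 0.12 against 0.01 ± 0.02 (SD, n = 4 each, exact permutation p = 0.0286, Benjamini-Hochberg adjusted 0.429) and was the 1 chromosome with an unadjusted p under 0.05. By Lkb1 status 0 chromosomes reached that level, and limma called 0 chromosomes after adjustment in both comparisons, with 0 by Lkb1 and 1 by PAX8 at an unadjusted p under 0.05. The 5 Mb window that differed most by Lkb1 lay on chromosome 13 from 120000001 to 125000000 (-0.25 ± 0.35, n = 5, against -0.74 ± 0.27, n = 3, exact max-statistic permutation p = 0.411). By PAX8 it lay on the same chromosome from 110000001 to 115000000 (-0.57 ± 0.32 against -0.09 ± 0.08, SD, n = 4 each, exact max-statistic permutation p = 0.4).

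Single windows were shared by more tumors than shifted profiles gave. The most shared gain and the most shared loss each reached 8 of 8 tumors, against a median of 4 for gains and 5 for losses over 10000 random shifts (one-sided permutation p = 0.0001 for both, the smallest they can give). Shifting also breaks any offset of all libraries against the reference at fixed positions, so this p does not show that the tumors changed there. Of windows with at least 10 bins, a filter chosen after seeing the data, the gain on chromosome 3 from 15000001 to 16000000 was in 8 tumors, and the highest loss was in 7. In 5 Mb windows the most shared loss was in 5 tumors and no longer passed (one-sided permutation p = 0.204), and the most shared gain was also in 5 (one-sided permutation p = 0.0445). Sharing of broad changes was weaker: 0 chromosomes were altered the same way over most of their windows in at least 4 tumors, and loss of chromosome 13 came closest, in 3. The lowest window in all 5 Lkb1-deleted tumors was 1 bin on chromosome 12 from 18000001 to 19000000 (log2 -2.83 to -2.22). Of all 8 tumors 7 were below -0.2 there, among them 2 Lkb1-intact tumors, and no difference by Lkb1 was tested at this bin.

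The labels name Lkb1 as the gene that differs between tumors, and Stk11, Trp53 and Brca1 were among the genes followed as edit targets fixed in advance. A difference in Stk11 copy number by Lkb1 label did not pass the test. The 1 bin over Stk11 (chromosome 10, gene from 80115767 to 80130679) read -0.21 ± 0.33 (SD, n = 5) in Lkb1-deleted and 0.04 ± 0.12 (SD, n = 3) in Lkb1-intact tumors, with an exact two-sided permutation p of 0.25. Lkb1-deleted tumor 4 read -0.71 and tumor 5 read -0.37, while the other 3 Lkb1-deleted tumors lay between -0.05 and 0.10. The other bins within 1 Mb had a median of -0.36 in Lkb1-deleted tumor 4 and of 0.02 in Lkb1-deleted tumor 5. Chromosome 10 was lost in Lkb1-deleted tumor 4 (mean log2 -0.41), and without that tumor the Stk11 difference moved from -0.25 to -0.13. Over bins within 1 Mb it was -0.12. Trp53, which encodes the p53 tumor suppressor, read -0.21 ± 0.16 (SD, n = 5) and -0.22 ± 0.17 (SD, n = 3) in the deleted and intact groups. Trp53 also lies in 1 bin. The other bins within 1 Mb had medians from -0.19 (Lkb1-deleted tumor 1) to 0.09 (Lkb1-intact tumor 3). Means of all bins within 1 Mb ran from -0.31 to -0.02 in the same tumors. The single bin thus does not show that the locus was lost in either group. Brca1, a homologous recombination gene, read -0.10 ± 0.12 (SD, n = 5) and 0.16 ± 0.05 (SD, n = 3) in the deleted and intact groups. Edits of a few bases cannot be seen in bins of this size, which have a median length of 18627 bp.

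High single values stood at 2 oncogenes. Ccne1, which encodes cyclin E1, lies on chromosome 7 from 38097984 to 38107490 in 1 bin that read 5.14 in Lkb1-intact tumor 1, 4.78 in Lkb1-intact tumor 3, 4.08 in Lkb1-deleted tumor 4 and 3.60 in Lkb1-deleted tumor 2. It read 0.98 in Lkb1-deleted tumor 1 and between -0.30 and 0.03 in the other 3 tumors. The other bins within 1 Mb had medians of -0.57 to -0.06 in the 4 tumors with the highest values. Myc, which encodes a transcription factor of cell growth, read 1.87 in Lkb1-deleted tumor 5, inside a gain of 5 bins on chromosome 15 from 60000001 to 62000000 (median log2 1.65). Mycn (-1.01), Akt1 (-1.02) and Cdkn2b (-1.14) fell below -1 in Lkb1-deleted tumor 1, each in 1 bin. Mycn and Akt1 lie on chromosome 12, lost in that tumor (mean log2 -0.73), and the other bins within 1 Mb had medians of -0.65 and -0.68 there. The neighbour of Cdkn2b, Cdkn2a, read 0.07 in Lkb1-deleted tumor 1, and the other bins within 1 Mb of Cdkn2a had a median of 0.03. The single Cdkn2b bin thus does not show that its locus was lost. The Mycn bin was below -0.2 in 6 of 8 tumors. Altogether 20 of 96 measured list genes, such as Pik3r1 (mean log2 -0.33), Prkaa1 (0.28) and Rab25 (0.27), were past 0.2 the same way in at least 4 tumors. That share, 20.8%, lay below the 33.7% of all 18475 genes, and among genes of 4 or more bins it was 9.09% against 9.62%. By the 1 Mb window that holds each gene, 10 of 22 homologous recombination genes were lost and 3 gained in Lkb1-deleted tumor 4, 9 lost and 1 gained in Lkb1-intact tumor 2, and 8 lost and 1 gained in Lkb1-deleted tumor 1. In these 3 tumors 26.1% to 32.0% of all windows were lost. Lkb1-intact tumor 3 went the other way, with 1 of these genes lost and 5 gained, and the PAX8-negative tumors had 0 lost by these windows. Of 17 PI3K, mTOR and LKB1 genes, at most 6 were lost by the same windows, in Lkb1-intact tumor 2, and at most 5 gained, in Lkb1-deleted tumor 4. Oncogene windows averaged 0.06 log2 above tumor suppressor windows over the 8 tumors (two-sided permutation p = 0.0977).

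**Figure D3:**
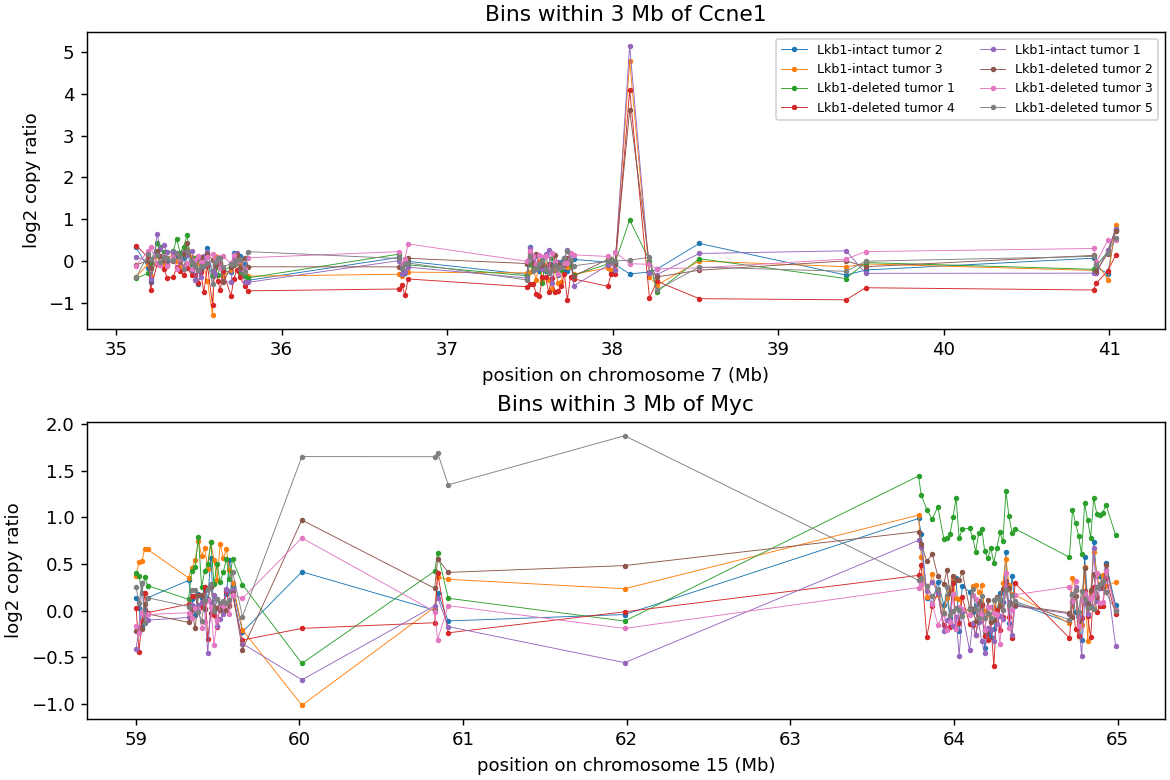
Log2 copy ratio (y axis) of each bin within 3 Mb of Ccne1 on chromosome 7 and of Myc on chromosome 15 (x axis, Mb), 1 line per tumor. The Ccne1 bin stands alone at 3.60 to 5.14 in 4 tumors, and the bins at Myc are raised together in Lkb1-deleted tumor 5.

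The authors' deposited table named 9 ascites clusters, with 1991 marker entries, and all values from it are average log fold changes of 1 library without replicates, read as natural logs. How doublets were treated is not given in the sources used here. The cluster named tumor cells held 572 markers, led by Mt2 (2.92), Clu (2.88) and AC131339.2 (2.77) in the authors' deposited table. It listed 8 of 20 epithelial markers, such as Krt7 (2.71), Krt18 (2.62) and Epcam (1.69), and 9 of 10 mesothelial markers, such as Upk3b (2.21) and Wt1 (1.92), in the authors' deposited table. Its entry for a tdTomato reporter stood at 1.65 in the authors' deposited table, and Pax8 was not among its markers. The cluster named CAFs held 8 of 12 fibroblast markers, led by Csrp2 (2.96) and Col1a2 (2.71) in the authors' deposited table.

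Immune clusters mostly carried the markers of their names. B-cells held 12 of 12 B cell markers, T-cells 14 of 16 T cell markers and erythrocytes 7 of 7 erythroid markers. The first of the macrophage clusters held 9 of 12 macrophage markers and was led by Saa3 (2.28) and Marco (2.05) in the authors' deposited table. The second macrophage cluster held 5 of 10 monocyte and 2 of 12 macrophage markers and was led by the MHC class II genes H2-Ab1 (2.21) and H2-Aa (2.18) in the authors' deposited table. The cluster named monocytes held 11 of 12 neutrophil markers and 1 of 10 monocyte markers, and was led by Retnlg (4.04), S100a9 (3.99) and S100a8 (3.96) in the authors' deposited table. The cluster named dividing cells held 7 of 8 cycling markers and as many, 7 of 8, markers of conventional dendritic cells of the Xcr1 type, with 7 of 7 MHC class II genes. B-cells (215 markers) and T-cells (220) shared 110 markers. The largest overlap was between tumor cells (572 markers) and CAFs (360), which shared 114.

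Regions called as gained in the ascites tumor cells, read from state numbers above 3, were not higher in the DNA of the tumor from the same mouse than regions called as lost. Over the measured 1 Mb windows they overlap, weighted by the overlap, the 20 gain regions had a mean WGS log2 ratio of 0.03 in Lkb1-deleted tumor 1 and the 9 loss regions 0.10, a difference of -0.07 (one-sided permutation p = 0.73). That this tumor and the ascites come from 1 mouse rests on the number in their labels alone, and a wrong number was not excluded. Other causes of the mismatch were not excluded either. Tumor cell markers made up 15.1% of genes in gain regions and 3.25% in loss regions, and the tumor cell cluster listed 9 of 10 mesothelial markers. The difference in Lkb1-deleted tumor 1 was the lowest of the 8 tumors, but the spread over shifts varied between tumors. Lkb1-intact tumor 1 had the highest one-sided permutation p (0.971). The highest value, 0.16, was in Lkb1-deleted tumor 4 (one-sided permutation p = 0.0886, adjusted 0.709 over 8 tumors). In Lkb1-deleted tumor 1, 6 of the 29 regions were past 0.2 the same way, among them all 3 gains on chromosome 15 (0.38 to 0.42), and 6 were past it the opposite way. Gains were called on chromosome 8 from 88118769 to 95807462 and on chromosome 18 from 74268272 to 88927481, where Lkb1-deleted tumor 1 read -0.66 and -0.59. The oncogenes Pik3ca, Braf and Akt1 lay in gain regions, but the region that holds Akt1 read -0.68 in Lkb1-deleted tumor 1. Of 31 tumor suppressors Cdk12 lay in a gain region and Tsc1 in a loss region. Markers of the tumor cell cluster lay at -0.04 log2 in Lkb1-deleted tumor 1 and immune markers at -0.03 (difference -0.02, two-sided permutation p = 0.476).

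**Figure D4:**
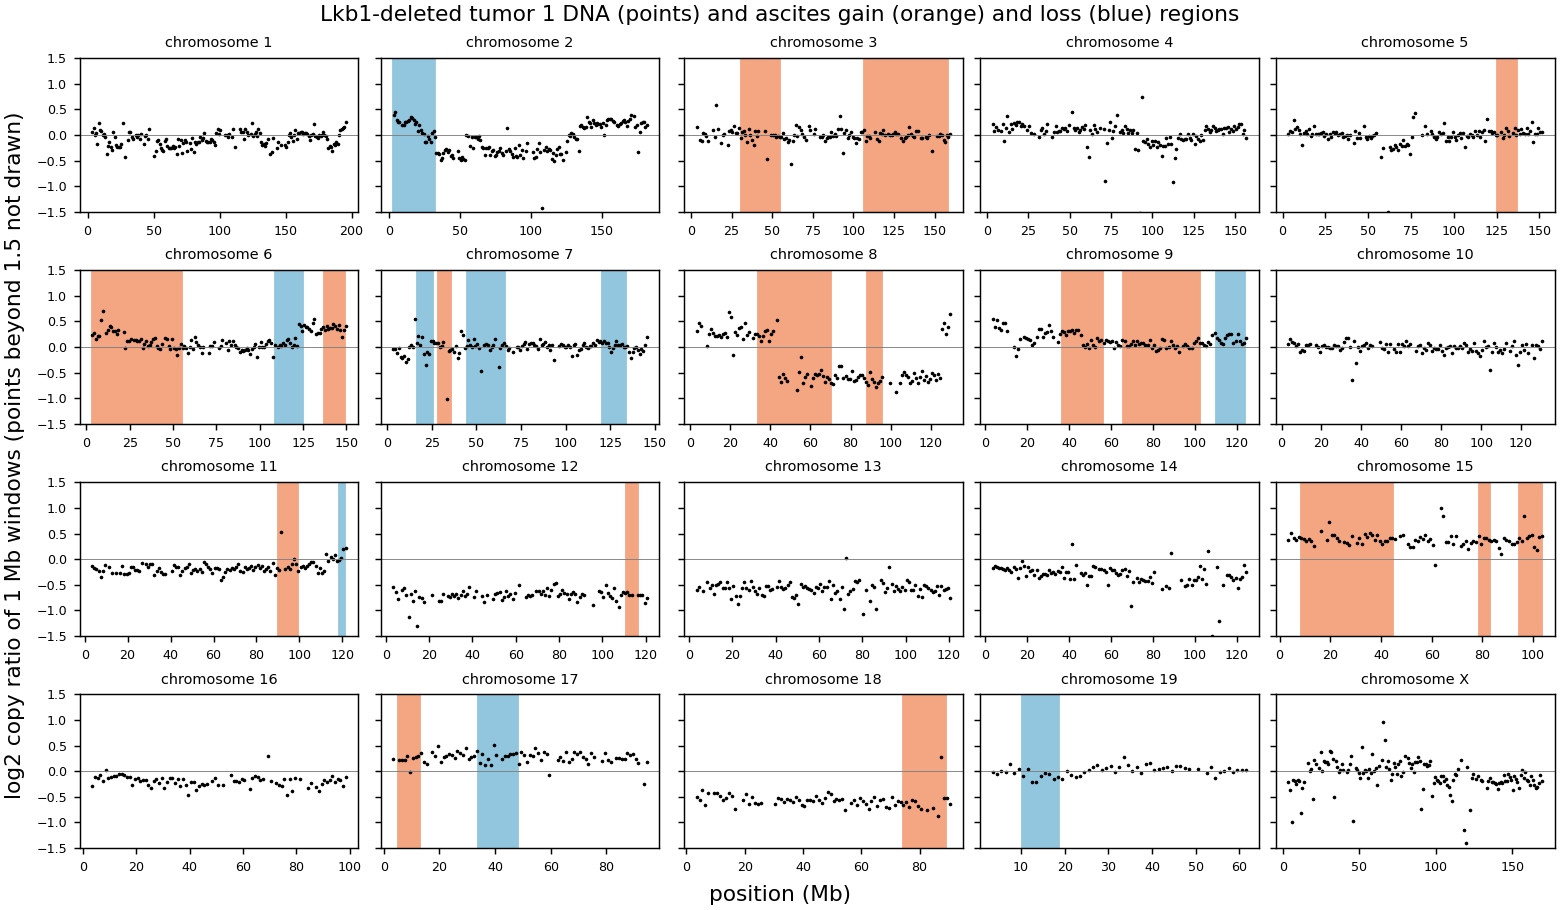
Log2 copy ratio of 1 Mb windows of Lkb1-deleted tumor 1 (points, y axis) along each chromosome (x axis, Mb), with gain regions (orange) and loss regions (blue) called in ascites tumor cells of the same mouse. Gains match raised windows on chromosome 15, while chromosomes 12, 13 and 18 are lost in the tumor with no loss region on them.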

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

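All tests of explanations in this part were chosen after the results were seen. Over 42 checks of a group for a sample far from the others, 2 stood out, and chance flags about 1 in 20. Lkb1-intact tumor 3 had 34.9% of windows altered, apart from the other 3 PAX8-positive tumors, of which the nearest had 45.9%. Akt1 read -1.02 in Lkb1-deleted tumor 1, where the nearest of the other Lkb1-deleted tumors read -0.23, and its bin lies on chromosome 12, which is lost in that tumor.

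The larger altered share of PAX8-positive tumors was weighed against noise and against the share of tumor cells. Noise that is independent between bins should average out in longer windows. The PAX8 difference in 5 Mb windows was 106% of that in 1 Mb windows, which argues against such noise as the whole cause. Errors shared by neighbouring bins would not average out, so the comparison cannot decide about them or about depth in general. A tumor cell share up to about 3-fold lower in PAX8-negative samples may shrink their changes: the highest had 30.0% of 5 Mb windows past 0.1, above the lowest PAX8-positive tumor past 0.3 (12.5%), while the means were 16.2% and 24.1%. The longest runs of PAX8-negative tumors went both ways against those of PAX8-positive tumors (losses -0.73 to -0.41, gains 0.35 to 0.40, over 23 to 113 windows). Some were as deep (losses -0.62 and -0.71 in Lkb1-deleted tumors 2 and 3, gains 0.38 in Lkb1-deleted tumor 5 and 0.71 in Lkb1-intact tumor 1). Others were shallower (losses -0.36 in Lkb1-deleted tumor 5 and -0.35 in Lkb1-intact tumor 1, gains 0.31 and 0.28 in Lkb1-deleted tumors 2 and 3). The runs at -0.71, 0.71, -0.35 and 0.28 spanned only 2 to 5 windows and say little about the share of tumor cells. That explanation stays open. A difference tied to PAX8 status itself also stays open, as untested.

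The single high bin at Ccne1 was weighed next. An amplified segment reaching neighbouring genes needs them raised too, and the highest median of the other bins within 1 Mb among the 4 tumors with the high bin was -0.0567. Reads misplaced at this bin in every library are argued against by 3 tumors at or below 0.2. Copies of the gene sequence outside its locus may give such a bin, and with 1 bin over the gene this cannot be told apart from a very short amplified segment. No biological explanation was tested.

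Windows altered the same way in most tumors may be differences between all these libraries and the reference. Of 32 windows altered in at least 6 of the other 7 tumors, 40.6% were altered the same way in Lkb1-deleted tumor 3, which had 3.71% of all windows altered. This lies under the 50% set for that explanation and above the bound that would argue against it, so the question stays open, and with each of the other 7 tumors left aside in its place the share was 59.1% to 100%. The 32 windows held a median of 5.5 bins, against 26 over all windows, and of the 9 with at least 10 bins 66.7% were altered there. No biological explanation was tested.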

How the results depend on the processing

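Tests on windows with at least 10 bins, with bins of depth 0 kept and within endings of the tumor numbers were chosen after seeing the data. The PAX8 difference in altered share stayed positive in every alternative and at an exact p of 0.0286 under thresholds of 0.1 (39.4 points) and 0.3 (22.7 points), recentring, 5 Mb windows and autosomes only. Within Lkb1 groups it was 34.5 points (exact p = 0.0667, the smallest possible), and within number endings 36.3 points (exact p = 0.333, also the smallest possible). Leaving out each tumor gave 32.5 to 37.5 points with an exact p of 0.0571, the smallest that 3 against 4 tumors allow, so those losses of the call follow from fewer samples. The Lkb1 difference in altered share turned to 2.85 points within PAX8 groups, and ran from -16.7 to 2.32 points when each tumor was left out, the highest without Lkb1-intact tumor 2; the cause was not tested. In 5 Mb windows the most shared loss fell to 5 tumors (p = 0.204 by permutation) and the most shared gain to 5 (p = 0.0445), and the cause was not tested. At a threshold of 0.1, 1 chromosome was altered the same way in at least 4 tumors, against 0. Direction and side of the threshold stayed in 173 of 187 comparisons with an alternative. Of these, 54 could not have crossed the threshold, since too few splits or the adjustment over chromosomes forbid it. Of 117 that could cross it, 115 stayed. This last count is about the threshold and does not measure how stable directions were: the direction turned in 2 of the 187, both for the Lkb1 altered share. Recentring cannot move a difference between regions or gene lists of 1 tumor, and the 0.5 limit on markers removes nothing, so these (4) say nothing about stability. Filtering markers by share of cells and choosing 1 tumor cluster among several were not run, since the table has no such share and 1 such cluster. The labels do not say that replicate numbers pair the tumors, so the splits within number endings are the closest to a paired fit. Depth limits what a single bin can show.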

Other observations

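All tests in this part were chosen after the results were seen, except the planned comparisons of chromosomes and 5 Mb windows. The first of the macrophage clusters carried 5 of 9 complement and lipid genes and Arg1 (1.91) among its markers in the authors' deposited table. The cluster named monocytes carried 6 of 11 immediate early genes, a list fixed as a sign of handling. Tumor cells and CAFs both listed Cdk4 (1.01 and 0.93) and Ccnd2 (1.16 and 0.71) in the authors' deposited table.

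Tumor cell markers made up 15.1% of the genes in ascites gain regions and 3.25% of those in loss regions. Both come from expression in the same cells, so this overlap follows in part from how such regions are called and is no independent test. A gain was also called in cells of cluster 5, on chromosome 17 from 31647082 to 35704621, where 13 of 74 genes were H2 genes and 10 were markers of that cluster. Another was called in T-cells on chromosome 14 from 79481194 to 122021034, where 0 of 22 genes were H2 genes or markers of that cluster.

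Brca1 had an exact permutation p of 0.0357 between Lkb1-deleted (n = 5) and Lkb1-intact (n = 3) tumors, a test that was not planned. Over the 4 genes tested this way the Benjamini-Hochberg adjusted value was 0.143. By the mean of all bins within 1 Mb of Brca1 the groups overlapped, with Lkb1-intact tumor 2 at -0.04 and Lkb1-deleted tumor 3 at 0.01. The bins of Cwc22 on chromosome 2 read above 3 in Lkb1-intact tumors 1 and 2 and in no other tumor, and a C1ql2 bin read 5.02 in Lkb1-deleted tumor 5.

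By PAX8, 1 chromosome had an unadjusted exact p under 0.05, and 14 of 35 splits gave as many, up to 4. The largest 5 Mb difference by Lkb1 was 0.49, and 23 of 56 splits gave as much, up to 0.90. By PAX8 it was 0.48, and 14 of 35 splits gave as much, up to 0.84. Chance cannot be excluded for these 3 results. By Lkb1 the count of chromosomes was 0, which any of the 56 splits reaches, so it tests nothing; the highest other split gave 4.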
